A study of Danio rerio with 6 samples.

How the data were processed

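Whole zebrafish larvae of strain C32 were compared at 6 days post-fertilization between pools kept germ-free and pools that were raised germ-free to day 3 and then colonized with the microbial community of conventionally reared zebrafish until day 6. Each of the 2 groups had 3 biological replicate pools of 28 to 80 larvae, per the labels' protocols, and each pool was hybridised to its own array, so a replicate is a pool and not a single larva. Per the labels' protocols, 12 ug of total RNA per pool was turned into biotin-labelled cRNA by in vitro transcription, and 20 ug of cRNA per array was hybridised to a 1-colour Affymetrix zebrafish array. Groups and replicate numbers were taken from the labels.

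The deposited values are intensities on a linear scale. Per the series' design text, the authors normalized the arrays with the invariant set method and summarised each probeset with the PM-MM model in dChip, which subtracts mismatch from perfect match probes. The invariant set method assumes that a set of probes keeps its rank across arrays, so a change shared by most genes would be removed. The authors' present and absent calls and the scanner files were not used here. Median intensities per array lay between 86.0 and 93.8, and 2831 to 3062 probesets per array lay below an intensity of 32. For every pair of arrays, the number of probesets with identical values was 0. For arrays, the number of pools limits the precision.

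The table holds 15617 probesets. Of these, 115 control probesets were left out and 15502 were tested, with no filter on dim probesets. Gene symbols came from the platform annotation, which can be old, and were updated through Entrez identifiers with a table of the GRCz12tu assembly, used for names only. A single symbol belonged to 10795 tested probesets, several symbols to 135 and none to 4572; 10711 of the 10795 were found in the reference table and 1 symbol changed. They stand for 8793 genes, of which 1539 have more than 1 probeset. No gene was named from a probeset with several symbols or none.

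Intensities were transformed to log2(intensity + 32), and every fold change given on the log2 scale is on this scale, which understates changes of dim genes. The limit of 1.5-fold was applied on this scale too. A linear model with the group as its only term was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow an intensity trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 15502 probesets, and a probeset was called changed at an adjusted p under 0.05. All adjusted p-values of probesets and genes come from this limma fit, and effects are colonized minus germ-free.

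Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, on 1 probeset per gene (the one with the highest mean log2 value over the 6 arrays), for lists with at least 5 measured genes, adjusted over 29 lists. The same lists were tested with the correlation estimated from the data and with fry. The lists cover acute phase proteins, complement, NF-kB and inflammatory mediators, neutrophil and macrophage markers, interferon response and antigen presentation, antimicrobial and redox defence, xenobiotic and bile acid metabolism, lipid transport and fatty acid oxidation, cholesterol synthesis, fasting response and gluconeogenesis, exocrine pancreas enzymes, markers of enterocytes, secretory epithelium, hepatocytes, muscle, neurons, photoreceptors and lens, erythrocytes, epidermis, skeleton and pigment cells, cell cycle, circadian clock, heat shock, unfolded protein response, hypoxia and glycolysis, glucocorticoid response, interleukin-17 and lymphoid genes, and ribosomal proteins. The last list was taken by a symbol pattern, which also took ribosomal protein kinases, and 1 lymphoid symbol was matched through a synonym to polr1g, which is no lymphoid gene. Counts of called members use the adjustment over all probesets, and counts adjusted over the list alone are given beside them.

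The lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule names the 12 genes with the largest rise and the 12 with the largest fall among called probesets with 1 symbol, with groups that do not overlap and a mean intensity of at least 100 in the higher group. It adds up to 4 called members of each list with the largest absolute change, and a fixed set of genes whatever their result. For a gene with several probesets the called one with the highest mean intensity was named, whereas list counts use the probeset with the highest mean log2 value, called or not, so that mpx, insig1, fosab and cyp1c1 are called by the rule and not in the list counts. For prdx1 the 2 measures of brightness picked different probesets, both called. Of the fixed set, cfb, hamp, il1b, tnfa, myd88, cpt1aa, hmgcra, cyp7a1 and per1a had no matching probeset and are not analysed here.

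The alternatives were pseudocounts of 16 and 100, the upper part of the probesets by mean intensity, quantile normalization, median centring, no intensity trend, array weights, no moderation of variances, the replicate number as a block, an added limit of 1.5-fold, and leaving out each array in turn. For lists, an estimated correlation, fry and the mean of a gene's probesets were added. The procedure was tested on simulated data in 10 runs with 200 changed probesets each. Means were those of the real probesets, and variances were drawn from the prior that limma fitted to these arrays. It recovered 41.8% of changes of 0.5, 96.3% of changes of 1 and 100% of changes of 2 on the log2 scale. Of the calls 4.34% were false, and at most 2 probesets were called in 5 simulations with no change. Simulated errors were normal, independent and of equal spread in both groups, as the model assumes. These shares therefore hold only where the real arrays meet those assumptions. In the simulation a shifted list of 60 genes was called in 10 of 10 runs and 0 of 280 unshifted lists were called, but simulated genes were independent, so this says nothing about lists whose genes vary together between pools. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.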

Results

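The expression of genes in whole zebrafish larvae was measured on 6 arrays, 3 from germ-free pools and 3 from pools colonized with a conventional zebrafish microbiota from day 3 to day 6 after fertilization. The comparison asks which transcripts differ with the presence of a microbiota at day 6. Pearson correlations of log2 values between arrays of a group averaged 0.988 to 0.990 for the colonized pools and 0.977 to 0.985 for the germ-free pools, and germ-free replicate 3 had the lowest value, 0.977. The first principal component, with 42.5% of the variance, separated the groups; the second, with 25.1%, set germ-free replicate 2 against germ-free replicate 3. The array number in the label of germ-free replicate 3 is out of run with the other 5, and no label says whether it was processed apart. As a sign of RNA quality, the log2 ratio of the 3' to the 5' control probeset of acta1 was higher in the colonized pools (2.79, 2.98 and 3.00) than in the germ-free pools (2.35, 2.47 and 2.64). The same ratio for gapdh overlapped between the groups, at 0.274 to 0.485 in colonized and 0.308 to 0.603 in germ-free pools. The acta1 ratio was taken with the dimmer of its 5' probesets, AFFX-Dr-acta1-5_at. Its means of 2062 in germ-free and 1558 in colonized pools lie far above the array medians of 86.0 to 93.8. A brighter 5' probeset, AFFX-Dr-acta1-5_x_at, had 8518 and 8807 in the same order, and the 3' probeset 11516.5 and 11775. Whether the brighter 5' probeset measures acta1 alone was not tested, so its values do not set the difference aside. With the dimmer probeset, the difference runs along with every gene group described here.

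Colonized larvae had higher levels of 13 of 18 acute phase transcripts, 9 of 18 complement transcripts and 10 of 26 neutrophil and macrophage markers. Of 47 transcripts of lipid transport and fatty acid oxidation, 10 were lower and 4 higher. The heme-binding hemopexin gene hpxa rose from a mean intensity of 26.5 ± 3.67 to 306 ± 128 (SD, n = 3 pools per group), and the serum amyloid gene saa from 22.9 ± 2.79 to 205 ± 43.8. The matrix metalloproteinase gene mmp9 rose from 74.9 ± 6.19 to 537 ± 138. In the other direction, angptl4, an inhibitor of lipoprotein lipase, fell from 956 ± 13.6 to 338 ± 56.3, and fabp2, the intestinal fatty acid binding protein, from 2158 ± 70.12 to 972 ± 26.1. Of 15502 probesets, 263 changed at an adjusted p under 0.05, 199 higher and 64 lower in colonized larvae, for 143 and 50 distinct genes. On intensities with 32 added, changes of at least 1.5-fold were found for 151 of the higher and 43 of the lower probesets. Dim probesets can change more than this in intensity and still be left out. In all 263, the pools of one group lay beyond those of the other, which held for 19.6% of all tested probesets where chance gives 10% for 3 against 3. At an unadjusted p under 0.05 the count was 2050. The split between directions moved with scaling: 75.67% of calls were higher with the authors' normalization and 61.41% after quantile normalization (191 higher, 120 lower). The count was 173 without germ-free replicate 1, 410 without germ-free replicate 3, 137 without colonized replicate 1 and 114 without colonized replicate 2. Without moderated variances 5 probesets passed, and with array weights 569.

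**Figure D1:**
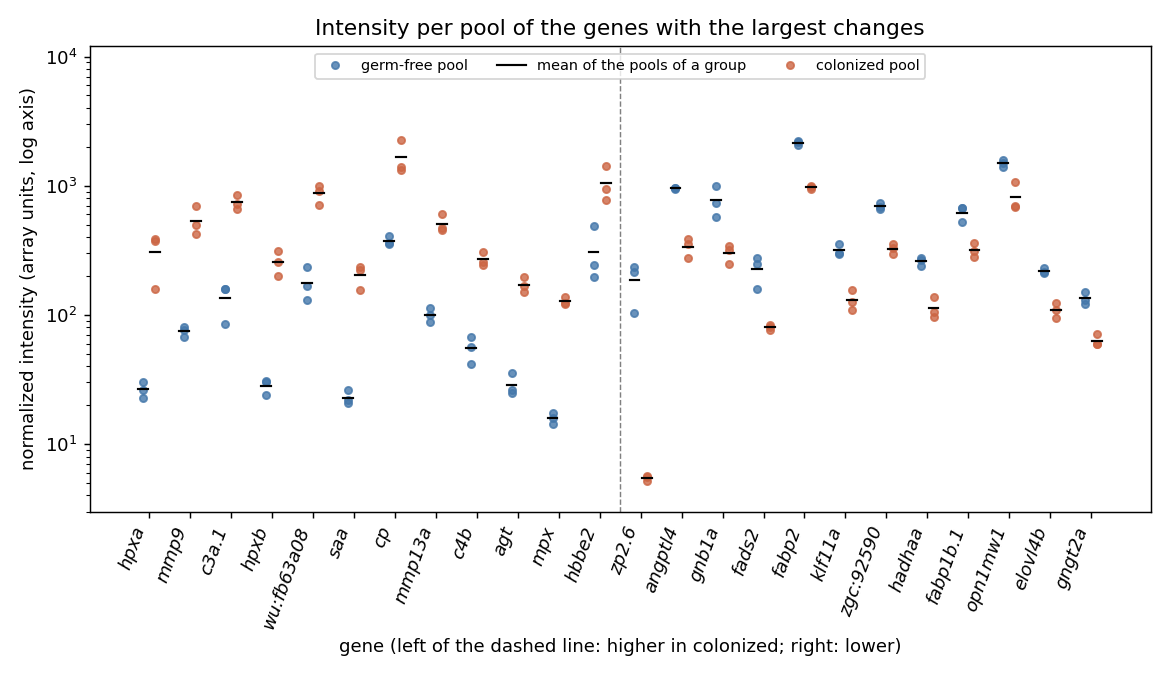
Normalized intensity on a log axis for the 12 genes with the largest rise and the 12 with the largest fall; each point is 1 pool (3 per group) and each bar the mean of a group. In each of these genes the colonized pools lie beyond the germ-free pools, with hpxa from a mean of 26.5 to 306 and zp2.6 from 185 to 5.48.

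The largest rises by the fixed rule, on the log2 scale, were hpxa (2.45 ± 0.25 SE), mmp9 (2.39 ± 0.16), the complement gene c3a.1 (2.25 ± 0.19), hpxb (2.24 ± 0.14), wu:fb63a08 (2.13 ± 0.18), saa (2.09 ± 0.13), ceruloplasmin cp (2.03 ± 0.18), mmp13a (2.02 ± 0.13), c4b (1.80 ± 0.13), angiotensinogen agt (1.74 ± 0.11), mpx (1.73 ± 0.09) and the globin gene hbbe2 (1.72 ± 0.29). Their adjusted p-values ranged from 1.43e-05 for mpx to 0.0148 for hbbe2. The call of mpx rests on 1 of 4 probesets, whose identifier shares its cluster number with the called cyp1a probeset, at 15.9 in germ-free and 127 in colonized larvae; the brightest mpx probeset had 166 and 224, a log2 change of 0.38 with an adjusted p of 0.1302. The largest falls were zp2.6 (-2.47 ± 0.21), angptl4 (-1.43 ± 0.12), gnb1a (-1.23 ± 0.18), the fatty acid desaturase fads2 (-1.19 ± 0.16), fabp2 (-1.13 ± 0.07), klf11a (-1.12 ± 0.13), zgc:92590 (-1.02 ± 0.10), hadhaa (-1.02 ± 0.12), fabp1b.1 (-0.89 ± 0.13), the cone opsin opn1mw1 (-0.87 ± 0.15), elovl4b (-0.84 ± 0.11) and gngt2a (-0.80 ± 0.10). Their adjusted p-values ranged from 3.57e-05 for fabp2 to 0.0160 for opn1mw1. Sizes and order depend on the added 32: with 16 and 100 added, hpxa had 2.83 and 1.63, hpxb 2.601 and 1.46, saa 2.49 and 1.301, agt 2.07 and 1.07, mpx 2.17 and 0.97, zp2.6 -3.15 and -1.40 and gngt2a -0.92 and -0.52. With 100 added, the largest rise of the 12 was that of cp (1.86). Of these 24 genes, hbbe2 was not called without germ-free replicate 1 or 2 or colonized replicate 1 or 3 (adjusted p 0.0550 to 0.0676). The fall of opn1mw1 was not called without germ-free replicate 1, colonized replicate 1 or colonized replicate 2 (adjusted p 0.0737 to 0.0977). A second probeset of gnb1a had a log2 change of 0.57 with an adjusted p of 0.528. Of 43 genes with several probesets and a call, 35 had all probesets on the same side of 0.

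Of 29 gene lists, 12 were called higher and 5 lower in colonized larvae with the preset correlation of 0.01. With an estimated correlation 0 of the 29 were called, and fry called 7. Other divisions of the 6 arrays into 3 and 3 called up to 16 lists and 0 probesets. The list tests at the preset correlation were thus also passed by groupings that mix germ-free and colonized pools. In each such division germ-free pools are still the majority on a side and colonized pools on the other. The 16 lists can therefore in part reflect the group difference and are no measure of false calls. The counts of called members carry the description of each list.

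Genes of the acute phase, proteins that the liver secretes during inflammation, rose together: 13 of 18 were higher, 0 lower and 5 not called, and 16 rose when adjusted over the list alone. The median log2 change was 0.94 (camera adjusted p = 8.08e-26; adjusted p = 0.0768 with an estimated correlation). Besides hpxa, saa and cp, the cytokine signalling suppressor socs3a rose from 147 ± 44.5 to 538 ± 10.9, and the fibrinogen chain fgb from 191 ± 38.8 to 496 ± 62.5. The fixed gene leap2 of this list was not called, at 135 and 151 (log2 change 0.13, adjusted p = 0.671). Of complement genes, 9 of 18 rose, 0 fell and 9 were not called; 10 rose when adjusted over the list alone. Their median was 0.44 (camera adjusted p = 7.37e-10; adjusted p = 0.0935 with an estimated correlation). Among them c3a.6 rose from 45.5 ± 7.98 to 197 ± 17.3 and the inhibitor cfi from 141 ± 15.95 to 452 ± 190. Markers of hepatocytes, the main source of both groups, rose in 10 of 34, with 0 lower and 24 not called; adjusted over the list alone 16 were higher and 1 lower. Their median was 0.32 (camera adjusted p = 7.00e-14, and 0.233 with an estimated correlation). Of the 34, 17 are members of other lists, such as cp and fga (314 ± 16.3 to 699 ± 70.9), as are 14 of the 18 acute phase genes. Of 24 hepatocyte genes outside the acute phase and complement lists, 3 were called higher. Most of the hepatocyte risers are therefore genes already counted above. Without colonized replicate 3 the hepatocyte median was 0.20.

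Of NF-kB and inflammatory mediators, 9 of 26 rose, 0 fell and 17 were not called; 15 rose when adjusted over the list alone. The median was 0.33 (camera adjusted p = 1.47e-11; adjusted p = 0.0609 with an estimated correlation). The NF-kB inhibitor nfkbiaa rose from 122 ± 18.2 to 309 ± 47.1, the transcription factor gene cebpd from 452 ± 132 to 1084 ± 91.2, and fosab from 113 ± 23.6 to 264 ± 62.2 on 1 of its 2 called probesets. The brightest of its 4 probesets, the one counted in the list, was not called (adjusted p = 0.0756). The rise of fosab was not called without germ-free replicate 1 or 2 or colonized replicate 1 (adjusted p 0.0541 to 0.0676). Called members of this list numbered 11 without germ-free replicate 3, 6 without germ-free replicate 1 or 2, 4 without colonized replicate 1, 3 without colonized replicate 2 and 5 without colonized replicate 3. Of neutrophil and macrophage markers, 10 of 26 rose, 0 fell and 16 were not called; 17 rose when adjusted over the list alone. The median was 0.47 (camera adjusted p = 3.25e-14; adjusted p = 0.0609 with an estimated correlation). Beside mmp9, mmp13a rose from 101 ± 13.0 to 509 ± 85.1 and lysozyme lyz from 121 ± 17.7 to 349 ± 137 (adjusted p = 0.0125). Of antimicrobial and redox genes, 5 of 26 rose, 0 fell and 21 were not called, with 6 higher and 1 lower adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.0104; adjusted p = 0.640 with an estimated correlation). The members that rose were lyz, the glutathione peroxidases gpx1b (210 ± 20.3 to 690 ± 175) and gpx1a, the peroxiredoxin prdx1 (277 ± 33.4 to 664 ± 158) and the thioredoxin txnb (143 ± 17.04 to 327 ± 57.3). Without colonized replicate 2 there were 3 risers, without colonized replicate 3 the median was 0.088, and without germ-free replicate 2 the list was not called (adjusted p = 0.0512). The intestinal alkaline phosphatase gene alpi.1 was not called, at 70.8 and 87.4 (adjusted p = 0.460). Of interferon response and antigen presentation genes 1 of 21 rose, the ubiquitin gene ubb (6091 ± 409 to 7637 ± 343), and the list was not called (adjusted p = 0.572; 1 higher adjusted over the list alone). In it 0 rose without germ-free replicate 1, colonized replicate 1 or colonized replicate 2. Of 7 measured interleukin-17 and lymphoid genes 0 were called, also when adjusted over the list alone; the list was not called (adjusted p = 0.589), and its median (0.04) and mean (-0.01) differ in sign.

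Genes of lipid transport and fatty acid oxidation moved both ways: 10 of 47 fell, 4 rose and 33 were not called, and 14 fell and 6 rose when adjusted over the list alone. The median was -0.13 (camera adjusted p = 1.69e-06; adjusted p = 0.386 with an estimated correlation). Those that fell were angptl4, fabp2, fabp1b.1 and apoa4b.2 and the fatty acid oxidation genes hadhaa (261 ± 19.9 to 113 ± 22.3), cpt1b, hadhb, etfdh, acadm and hadh; those that rose were apoeb, ucp2, ucp3 and the lipoprotein lipase lpla (193 ± 17.5 to 393 ± 27.9). Without colonized replicate 1 there were 6 falls, without colonized replicate 2 there were 5 falls and 1 rise, and without germ-free replicate 1 there were 2 rises. The apolipoprotein gene apoa4b.1 was not called, at 2723 and 2248 (adjusted p = 0.323). Of enterocyte markers 4 of 34 fell, 1 rose and 29 were not called, with 6 lower and 3 higher adjusted over the list alone. The falls were fabp2, fabp1b.1, the bile acid binding protein fabp6 (1113 ± 88.9 to 664 ± 81.6) and the retinol binding protein rbp2a (1103 ± 55.8 to 686 ± 95.2), and the rise was tm4sf4. The list as a whole was not called with all arrays (camera adjusted p = 0.166), and its median (0.01) and mean (-0.05) differ in sign. On leaving out 1 array, the list was called lower without colonized replicate 3 (camera adjusted p = 0.0112). Without germ-free replicate 1, colonized replicate 1 or colonized replicate 2 the fall of rbp2a was not called (adjusted p 0.0598 to 0.0852), nor was that of fabp6 without colonized replicate 2 (0.0648). In the enterocyte list 0 rose without either of colonized replicates 1 and 2, and 2 rose without germ-free replicate 3. Of exocrine pancreas genes 2 of 22 fell, zgc:92590 (693 ± 40.8 to 326 ± 28.6) and the carboxypeptidase cpa1 (775 ± 88.0 to 477 ± 73.3), 0 rose and 20 were not called; 5 fell adjusted over the list alone. The median was -0.18 (camera adjusted p = 1.28e-07; adjusted p = 0.330 with an estimated correlation). On leaving out germ-free replicate 1 or any colonized replicate the fall of cpa1 was not called (adjusted p 0.0677 to 0.114), and the median was -0.086 without colonized replicate 3. Of cholesterol synthesis genes 0 of 12 were called and 1 was lower adjusted over the list alone. The list was not called with all arrays (camera adjusted p = 0.0740). On leaving out 1 array, it was called lower without germ-free replicate 2 (camera adjusted p = 0.0170). Of insig1, 1 of 3 probesets rose (89.8 ± 10.15 to 152 ± 4.58), though not without colonized replicate 1 or 2 (adjusted p = 0.0579 and 0.0863). The gene hmgcs1 had 68.3 and 55.2 (adjusted p = 0.649). Of fasting and gluconeogenesis genes 3 of 28 rose, 1 fell and 24 were not called, with 8 higher and 2 lower adjusted over the list alone. The median was 0.15 (camera adjusted p = 0.0430; adjusted p = 0.330 with an estimated correlation). Without germ-free replicate 3 there were 6 rises. The list was not called without germ-free replicate 1 (adjusted p = 0.109), germ-free replicate 2 (0.0591) or colonized replicate 1 (0.0911). The rises were ddit4 (33.6 ± 7.63 to 109 ± 12.1), igfbp1b (573 ± 86.4 to 1106 ± 57.5) and igfbp1a, and the fall was cpt1b (61.2 ± 9.58 to 23.1 ± 2.84); pck1 had 1664 and 1996 (adjusted p = 0.374) and was called higher without germ-free replicate 3 (log2 change 0.44, adjusted p = 0.0101). Of xenobiotic and bile acid genes 4 of 30 rose and 2 fell, with 5 and 3 adjusted over the list alone, and the list was not called (adjusted p = 0.176). The cytochrome gene cyp1a rose from 473 ± 31.6 to 1014 ± 174 and the bile acid responsive repressor nr0b2a from 37.6 ± 9.24 to 137 ± 45.2 on 1 of 2 probesets, whereas cyp2k18 fell from 258 ± 37.1 to 135 ± 14.7, though not without colonized replicate 1 or 2 (adjusted p = 0.0601 and 0.0691). Without colonized replicate 2 there were 2 rises and 0 falls, and without colonized replicate 1 there was 1 fall.

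Of photoreceptor and lens markers 7 of 46 fell, 0 rose and 39 were not called; 10 fell adjusted over the list alone. The median was -0.15 (camera adjusted p = 1.12e-10; adjusted p = 0.0935 with an estimated correlation). The falls were opn1mw1 (1493 ± 93.4 to 818 ± 212), opn1sw2, gngt2a (134 ± 14.3 to 63.1 ± 6.51), gnb3b (491 ± 58.5 to 275 ± 60.3), gnat2 (1015 ± 144 to 625 ± 115) and guk1b, all photoreceptor genes, and the lens crystallin crybb1. Called falls numbered 2 without germ-free replicate 1, 2 without colonized replicate 1 and 1 without colonized replicate 2. The fall of gnat2 was not called without germ-free replicate 1 or 2 or colonized replicate 1 or 2 (adjusted p 0.0686 to 0.214), nor that of gnb3b without germ-free replicate 1 or colonized replicate 1 or 2 (0.0905 to 0.155). Of neural markers 2 of 44 fell, the tubulins tubb5 (331 ± 50.2 to 183 ± 45.9) and tuba2 (844 ± 26.3 to 546 ± 21.9, on 1 of 3 probesets), 0 rose and 42 were not called; 9 fell and 2 rose adjusted over the list alone. The median was -0.12 (camera adjusted p = 4.90e-06; adjusted p = 0.386 with an estimated correlation). Without germ-free replicate 3 there were 2 rises. The fall of tubb5 was not called without germ-free replicate 1, colonized replicate 1 or colonized replicate 2 (adjusted p 0.142 to 0.223), nor that of tuba2 without colonized replicate 2 (0.0634); the median was -0.075 without germ-free replicate 1. Of 37 cartilage, bone, collagen and notochord markers 0 were called, also when adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.00847; adjusted p = 0.566 with an estimated correlation). The median was -0.16 without germ-free replicate 2, -0.064 without germ-free replicate 3 and -0.066 without colonized replicate 2. Without colonized replicate 1 it was -0.058 and the list was not called (adjusted p = 0.0645), and without colonized replicate 3 there were 2 falls. Of muscle markers 1 of 51 fell, the creatine kinase ckmt2a (421 ± 30.1 to 240 ± 47.6), with 1 higher and 1 lower adjusted over the list alone; the list was not called (adjusted p = 0.518), and its median (0.02) and mean (-0.02) differ in sign. The muscle count was 2 without colonized replicate 3 and 0 on leaving out any other array but germ-free replicate 3. Of epidermis and ionocyte markers 5 of 53 rose and 1 fell, with 10 and 5 adjusted over the list alone, and the list was not called (adjusted p = 0.589); krt18a.1 rose from 393 ± 32.6 to 611 ± 50.1 and cldne fell from 151 ± 28.1 to 81.1 ± 8.20. Epidermal risers numbered 3 without germ-free replicate 1, germ-free replicate 2 or colonized replicate 3, 2 without colonized replicate 1 and 1 without colonized replicate 2. The fall of cldne was not called without germ-free replicate 1 or any 1 colonized replicate (adjusted p 0.0676 to 0.151), nor the rise of krt18a.1 without germ-free replicate 2 or any 1 colonized replicate (0.0529 to 0.0836). Of secretory and hormone genes 2 of 22 rose, the mucin muc5.1 (349 ± 20.1 to 538 ± 23.2, on 1 of 2 probesets) and glucagon gcga (66.9 ± 6.74 to 110.4 ± 7.21), with 5 higher and 1 lower adjusted over the list alone; the list was not called (adjusted p = 0.136). In it 1 rose without germ-free replicate 1 or colonized replicate 3 and 0 without colonized replicate 1 or 2. Of pigment cell markers 1 of 18 rose, the purine synthesis gene paics, also when adjusted over the list alone; the list was not called (adjusted p = 0.511), and its median (-0.04) and mean (0.0031) differ in sign. The pigment count was 0 without germ-free replicate 1 or 2 or colonized replicate 2 or 3.

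Of erythrocyte markers 2 of 22 rose, hbbe2 (308 ± 156 to 1051 ± 343) and the heme synthesis gene alas2 (146 ± 8.85 to 270.2 ± 64.2), 0 fell and 20 were not called; 10 rose adjusted over the list alone. The median was 0.21 (camera adjusted p = 7.13e-06; adjusted p = 0.386 with an estimated correlation). In this list 7 of 22 rose without germ-free replicate 3, 0 without germ-free replicate 1, germ-free replicate 2 or colonized replicate 1, and 1 without colonized replicate 2 or 3. Of glucocorticoid response genes 5 of 24 rose, 0 fell and 19 were not called, with 14 higher and 1 lower adjusted over the list alone. The median was 0.30 (camera adjusted p = 1.04e-08; adjusted p = 0.233 with an estimated correlation), and 12 rose without germ-free replicate 3. The risers were socs3a, cebpd, nfkbiaa, ddit4 and cebpb, which the inflammation or fasting lists also hold. The chaperone gene fkbp5 was not called, at 702 ± 355 and 1215 ± 161 (log2 change 0.88, adjusted p = 0.199), but was called higher without germ-free replicate 3 (log2 change 1.23, adjusted p = 0.0042) and with array weights (adjusted p = 0.0414). Of hypoxia and glycolysis genes 5 of 42 rose, 0 fell and 37 were not called, with 6 higher adjusted over the list alone. The median was 0.17 (camera adjusted p = 4.90e-06; adjusted p = 0.401 with an estimated correlation). They were ndrg1b (97.7 ± 18.1 to 280 ± 39.6), igfbp1a (808 ± 145 to 1505 ± 86.6), egln3 (18.3 ± 2.06 to 52.1 ± 5.79), hif1al and ero1a. On leaving out any array but germ-free replicate 3, 3 rose, and hif1al and ero1a were not called (adjusted p 0.0515 to 0.222). Of heat shock genes 1 of 30 rose, hsp70.3 (69.8 ± 14.96 to 177 ± 57.7), also when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.00769; adjusted p = 0.526 with an estimated correlation) and 3 higher without germ-free replicate 3, where the median was 0.22. The heat shock count was 0 without germ-free replicate 1 or 2 or colonized replicate 1 or 3, and the list was not called without germ-free replicate 2 (median 0.079, adjusted p = 0.0975). Of 29 circadian clock genes 0 were called, also when adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.0152; adjusted p = 0.330 with an estimated correlation). Without germ-free replicate 3, 2 of them rose and the list was not called (adjusted p = 0.0859), nor was it without colonized replicate 1 (0.0911). Of unfolded protein response genes 1 of 33 rose, ero1a (24.2 ± 3.32 to 44.6 ± 2.89), with 3 higher and 1 lower adjusted over the list alone; the list was not called (adjusted p = 0.603). In it 3 rose and 1 fell without germ-free replicate 3, against 0 called on leaving out any other array. Of 60 cell cycle genes 0 were called, also when adjusted over the list alone, and pcna had 622 and 549 (adjusted p = 0.707). The list was not called with all arrays (camera adjusted p = 0.140). On leaving out 1 array, it was called lower without germ-free replicate 3 (0.0288) or colonized replicate 3 (0.0130). Of 75 ribosomal protein genes 0 were called, also when adjusted over the list alone, and the list was not called (adjusted p = 0.307).

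**Figure D2:**
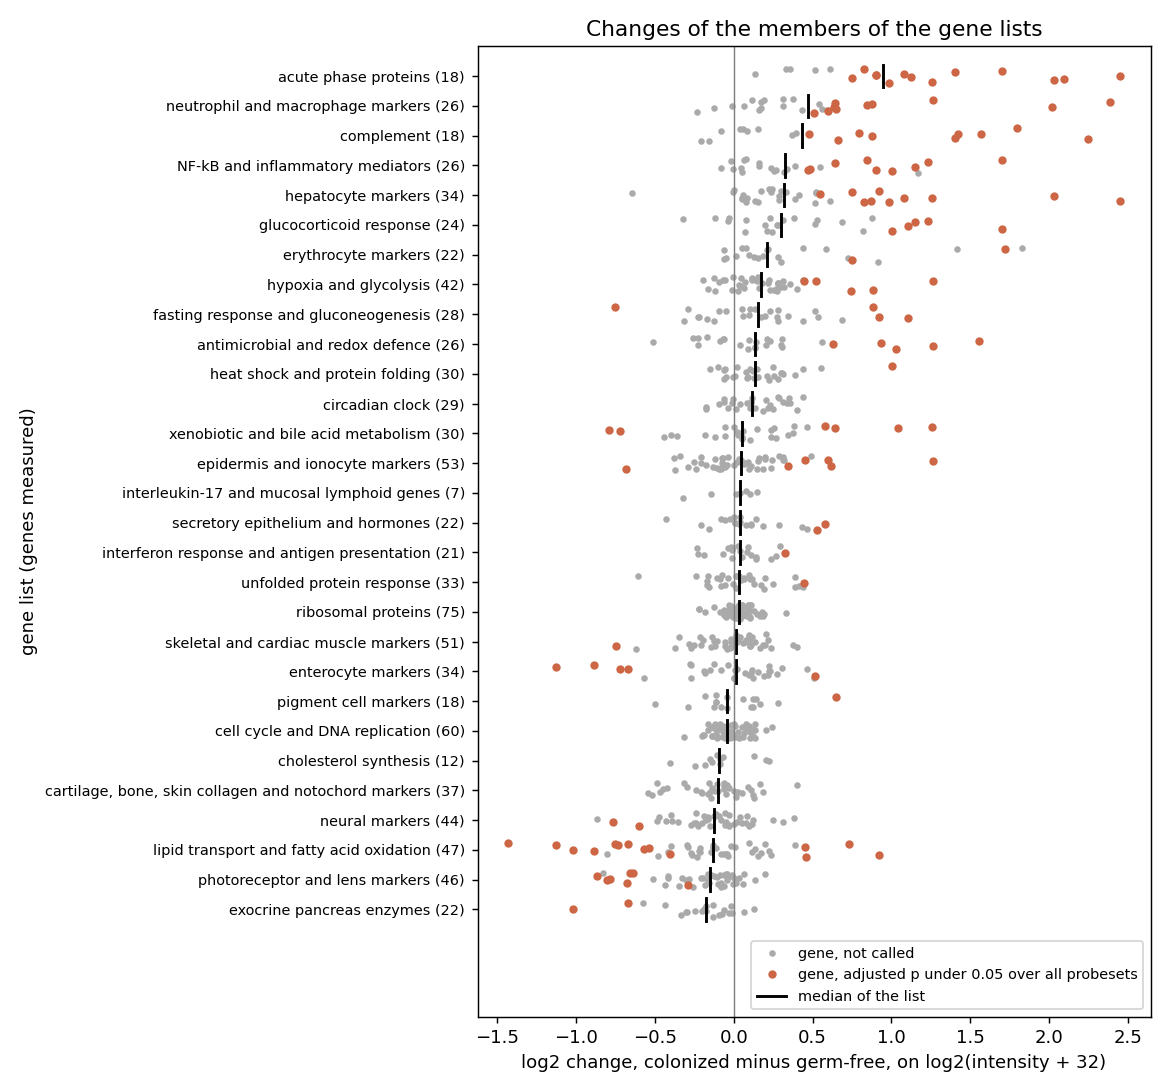
Log2 change (colonized minus germ-free, on log2(intensity + 32)) of each measured member of 29 gene lists, ordered by their medians; coloured points passed an adjusted p of 0.05 over all probesets, grey points did not, and black bars are list medians. The acute phase list has the highest median, 0.94, and the exocrine pancreas list the lowest, -0.18.

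Of the 4572 tested probesets with no symbol, 1 had the largest rise of all probesets tested, from 50.7 ± 5.26 to 1227 ± 285 (log2 change 3.91, adjusted p = 2.09e-06), and another rose by 2.15 on the log2 scale, from 78.4 ± 10.3 to 461 ± 96.7. The largest falls among them were -1.03 (238 ± 14.3 to 102 ± 30.3) and -0.97 (45.4 ± 7.86 to 7.55 ± 1.87).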

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

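All alternatives here were set before the data were examined, except, on leaving out 1 array, the gene list member counts, the gene sets drawn up later and the genes outside the lists. Under every alternative the 263 called probesets kept their direction, among those an alternative tested, and 0 of the named genes reversed. For called probesets this was mostly fixed in advance. Their groups did not overlap, so pseudocounts, array weights and leaving out 1 array could not reverse them. The trend, moderation, block, fold limit and choice of brighter probesets leave the estimate as it is. Only quantile normalization and median centring could have reversed a called probeset. The count of 263 (199 higher, 64 lower) was 266 and 267 with pseudocounts of 16 and 100, 275 without an intensity trend, 223 for the brighter probesets, 194 with a limit of 1.5-fold, 311 after quantile normalization (120 lower) and 293 after median centring (98 lower). Array weights gave 569 (365 higher, 204 lower). No moderation gave 5 (4 higher, 1 lower), with 1758 at an unadjusted p under 0.05; each probeset then has only 4 residual degrees of freedom. Leaving out 1 array gave 114 to 410 changed (98 to 326 higher, 16 to 84 lower): 173 without germ-free replicate 1, 410 without germ-free replicate 3, 137 without colonized replicate 1 and 114 without colonized replicate 2. The cause was not tested. Same-numbered pools deviated together weakly or not at all (correlations of deviations from the group means -0.0841, 0.0971 and 0.0693). Germ-free replicates 2 and 3 correlated best with their own number, and germ-free replicate 1 with colonized replicate 3 (0.0911). With so few pools this cannot show whether same-numbered pools share anything beyond the number. The replicate block gave 274 calls, 226 of them among the 263. The 17 called lists became 14 to 19 on leaving out 1 array, 0 with an estimated correlation and 7 with fry. Array weights kept all 17 in their direction and called 19 (12 higher, 7 lower). Quantile normalization and the replicate block each called 16 (11 higher, 5 lower). The mean of a gene's probesets called 17 (11 higher, 6 lower), 16 of them among the lists called in the main fit. Of 67 called named genes and 4 called probesets with no symbol, 22 passed no longer without colonized replicate 1, 22 without colonized replicate 2 and 17 without germ-free replicate 1; 69 did so without moderation. Signal over background limits dim probesets, which the added 32 shrinks.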

Other observations

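The splits of the arrays were chosen before their result was seen; the other tests here were chosen after the results they bear on were seen, and the limit to genes of a mean intensity of at least 100 was added after a first run over all genes. Genes outside the fixed lists, chosen after their values were seen, also changed. The coagulation factor gene f5 rose from 114 ± 19.4 to 348 ± 11.1, the phosphatidate phosphatase lpin1a from 605 ± 264 to 1588 ± 125 (not called without any 1 colonized replicate), and the metalloreductase steap4 from 76.8 ± 4.66 to 192 ± 32.5 (SD, n = 3 pools). The threonine dehydrogenase gene tdh rose from 1174 ± 215 to 2298 ± 143, and the protease gene ctsla from 1111 ± 118 to 2178 ± 109. The transcription factor klf11b fell from 78.1 ± 14.4 to 19.01 ± 5.76, as its paralog klf11a did. Of 17 zona pellucida probesets 1 was called, that of the egg coat gene zp2.6 (185 to 5.48), and the other 16 had log2 changes from -0.0884 to 0.289. The globin gene hbae3 was not called, at 1622 ± 1268 and 4999 ± 1437 (adjusted p = 0.0578), but was called higher without germ-free replicate 3 (log2 change 2.42, adjusted p = 3.10e-05). Among the 115 control probesets left out of the tests, AFFX-Dr-NM_131175-1_s_at had 1163 ± 104 in germ-free and 616 ± 171 in colonized larvae.

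For the number of changed probesets and of called lists, the 6 arrays allow 10 splits into 3 and 3, which is too few for a share under 0.05. The real split called 263 probesets and the highest of the others 0; 1 of the 10 splits reached the real count. The real split called 17 lists and the highest of the others 16, so 1 of the 10 reached the real count here too. Every other split mixes the groups, which adds the group difference to the spread within each side. The 0 called probesets were therefore largely fixed in advance and lend the 263 no support. The 16 lists can in part reflect the group difference, since each status is still the majority on a side.

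The rise of acute phase genes, with a median of 0.94, could come from a larger share of liver RNA. Against that as the whole cause, 21 hepatocyte genes outside the acute phase and complement lists had a median of 0.22 (95% bootstrap interval over genes 0.0855 to 0.391), below 0.472, the value midway to the acute phase median; 24 genes with no limit on intensity gave 0.231, or 0.122 without colonized replicate 3, and after quantile normalization the 21 gave 0.129. Without germ-free replicate 3, the array that stands apart, the acute phase median was 1.01. The bootstrap interval, like those in the paragraphs below, covers the spread over genes and not over pools. The hepatocyte set was not screened for liver genes that inflammation lowers, which would hold its median down. The median therefore counts against a larger liver share only as far as such genes are few. A smaller rise in liver RNA stays open, since 19 of those 21 hepatocyte genes lay above 0. The difference in microbial status that the design names stays open as the cause. It cannot be told apart here from other differences between the groups, such as the acta1 3' to 5' ratio taken with the dimmer 5' probeset.

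All 15 measured enzymes of fatty acid oxidation in a set drawn up after the values were seen lay below 0 in colonized larvae, also after quantile normalization and median centring (14 of 15 without colonized replicate 1), with a median of -0.477, and 6 of them were called. The tables argue against a lower level of mitochondrial genes as a whole, as the whole cause, since 76 respiratory chain and ATP synthase genes had a median of -0.0850 (interval -0.110 to -0.0421), above -0.239, the value midway. A smaller fall of that class stays open: 55 of the 76 lay below 0 while 2 were called higher (cox4i1l and cox6b1), and after quantile normalization 69 lay below 0, with a median of -0.157 (interval -0.181 to -0.108) beside -0.527 for the 15 enzymes. The median of the 76 was -0.0282 without colonized replicate 1, -0.0393 without germ-free replicate 1 and -0.128 without germ-free replicate 2. The difference in microbial status stays open as the cause. It cannot be told apart here from a difference between the groups in feeding or remaining yolk, which was not tested directly. The fasting and gluconeogenesis list moved both ways (3 of 28 rose and 1 fell) and does not decide this.

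The intestinal binding protein genes fabp1b.1, fabp2, fabp6 and rbp2a are the 4 called falls of the enterocyte list, and the smallest of the 4 was -0.67. Against a smaller share of enterocyte RNA as the whole cause, which would lower uncalled members by about as much, 25 genes of the list, these 4 included, had a median of 0.0696 (interval -0.179 to 0.220), above -0.334, the value midway to the smallest fall. All 34 genes gave 0.0146, and the 25 gave -0.0135 after quantile normalization, 0.0419 after median centring and -0.0142 without colonized replicate 3. Abundant members such as apobb.1 (2849 and 2865) and chia.1 (2025 and 2397) did not fall, but chia.2 (3113 and 2564) and ctsl.1 (1286 and 863) were lower without a call. The larvae were measured whole, and 11 of the 34 genes belong to other lists too. Transcripts from other tissues could mask a fall, so the comparison counts only as far as the members' transcripts come from enterocytes. A smaller fall in enterocyte RNA stays open, as does the difference in microbial status as the cause.

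Of the 34 photoreceptor genes of the photoreceptor and lens list, 30 lay below 0, with a median of -0.172, and 6 were called lower. After quantile normalization 32 lay below 0, with a median of -0.218. The pigment epithelium genes rpe65a, rgrb and rlbp1a of the list were counted neither here nor among the lens genes. In the list 7 of 46 genes lay above 0, 4 of them photoreceptor and 3 lens genes, so those left out did not rise. Of 9 lens genes 6 lay below 0, with a median of -0.0490, and 1 was called lower, crybb1; the median was -0.0836 after quantile normalization, -0.0767 after median centring and 0.0122 without colonized replicate 1. These values leave open less eye RNA, less photoreceptor RNA and a change of single genes. The light or time of day at collection was not tested directly. Of 29 circadian clock genes 0 were called, with a median of 0.12 (camera adjusted p = 0.0152, and 0.330 with an estimated correlation). These clock values do not decide the point.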
